A study of Mus musculus with 12 samples.

How the data were processed

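Liver RNA of 12 C57BL/6J mice was sequenced as poly(A) libraries (NEBNext Ultra II, 75 bp paired-end reads, NextSeq). The labels give 3 groups of 4 mice, and the replicate numbers link no animals between groups. Deviations of log2 CPM from the group mean, compared between libraries of the same replicate number, correlated at -0.22 to 0.19 between groups, above 0.1 in 2 of 12 cases, and 0 of 12 libraries matched best with their own number, so no pairing was used in the models reported.

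Each library has 1 table of 41325 genes. The deposited counts are whole reads per gene, split into total, unique, exon, junction and intron reads, and total gene reads equal exon plus intron reads. Whether a read pair counts as 1 or 2 is not stated. The authors also give TPM, which sum to the same total over the listed genes in each library, and RPKM, scaled by exon length with a denominator of its own per library. Per the file headers, each table also holds the fraction of unique and of intron reads. The submitters name the genome build GRCm38. The aligner, the counting tool and their settings are not given in the sources used here, and neither is the strand of the kit. Total gene reads were analysed, without any correction of the authors' values. RPKM was not used in a comparison.

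Totals were 28161100 to 33852300 reads per library, a 1.20-fold range. In edgeR 4.0.16 (R 4.3.3), genes were kept by filterByExpr by group (minimum count 10, minimum total 15, large n 10), which left 16456, and scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries with robust shrinkage, and each comparison was tested two-sided with Benjamini-Hochberg adjustment at 0.05. CPM are TMM-scaled, log2 CPM use a prior count of 2, and fold changes use edgeR's prior count of 0.125. Errors are SD over 4 libraries for CPM and SE for log2 fold changes. That SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It is not a standard error fitted by the model, and the 95% intervals of Kupffer cell genes rest on it. A count of 0 over a group allows up to 3 reads, and the size of such a change is given only as a lower bound at that floor.

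Of 36 gene lists, 34 had at least 5 tested genes and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry called 30, 16 and 28 lists in the 3 comparisons. Cell type lists are read as RNA levels in bulk liver, not as cell numbers. Some lists share genes, so their calls are not independent of each other. Lists, comparisons, tests, 15 alternatives and the rule for naming genes were fixed at the same time as the alternatives. The rule names the 8 largest rises and the 8 largest falls by fitted fold change, which for genes with 0 reads in a group depends on the prior count, among genes with adjusted p under 0.05, mean CPM of at least 1 and no overlap between groups, leaving out predicted genes, pseudogenes and immune receptor segments. It also names 18 key genes and up to 4 members per list with the lowest p. With 4 against 4 libraries, chance gives no overlap for 2.86% of genes, and 54.4%, 21.6% and 43.7% of the tested genes had none. For CDDO-Me against control the largest changes are given only as counts. Within this rule, list members with mostly shared reads or overlapping neighbours were left out after their values were seen. Results for some members of the gene lists are not reported here. Read support (unique, intron and junction reads) and overlapping genes were checked for every named gene.

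The opposite-sign count was set against independent lists, against 20 simulations in which CDDO-Me equals NASH vehicle, and against splits of the NASH vehicle libraries. Each comparison was repeated for all 35 splits of its 8 libraries into 4 and 4. On simulated data with the depth and spread of CDDO-Me and NASH vehicle, the model recovered 31.3%, 47.0% and 82.1% of genes changed 1.5-, 2- and 4-fold, with 2 false calls among 16146 genes.

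Before the data were examined, these alternatives were chosen: DESeq2 size factors, DESeq2 1.42.0, no filter, a filter of 50 reads in 4 libraries, the 8 libraries of the 2 groups, a replicate block, unique gene reads, limma-trend on log2(TPM + 1), limma-voom, a 2-fold minimum, leaving out each library, a prior count of 2, log2 of mean TPM + 1, estimated correlation and fry. Library totals without TMM, total exon reads and 10 libraries without control 3 and CDDO-Me 4 were chosen after seeing the data. So were 4 further gene lists (smooth muscle, female-type liver, male-type liver and aryl hydrocarbon receptor targets), the first after Acta2 and 4 of its own 12 tested genes had been seen in control 3, the next ones after 10 of 19 and 14 of 24 members, and the last after Cyp1a1, Cyp1a2, Nqo1 and Nfe2l2 had been seen. Counting Tagln, of which other values had been seen, 5 of the 12 smooth muscle genes had been seen in some form. Library measures were compared by two-sided exact permutation tests with Benjamini-Hochberg adjustment over 21 tests.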

Results

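RNA was measured in the livers of 12 C57BL/6J mice of wild-type genotype, 4 in each of 3 groups. Control mice received vehicle (control). Mice with diet-induced nonalcoholic steatohepatitis (NASH), a fatty liver disease with inflammation and fibrosis, received either vehicle (NASH vehicle) or CDDO-Me (bardoxolone methyl) by mouth at 10 mg/kg for 8 weeks (CDDO-Me). CDDO-Me is a synthetic triterpenoid that activates NRF2, the transcription factor encoded by Nfe2l2, by binding its inhibitor KEAP1. The series title names macrophage recruitment in NASH as its subject, and the design text asks how CDDO-Me protects the liver. Each library held between 28161100 and 33852300 reads on 41325 genes, of which 16456 had enough reads to be tested. A count of 0 reads over a group allows up to 3 reads, and this floor and the counting intervals cover counting error only.

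The 3 groups separated along the main axes of variation. The first principal component of log2 CPM (read counts scaled to the size of the library) held 65.6% of the variance and set the control libraries apart from both NASH groups, and the second held 9.78% and set the CDDO-Me libraries apart from the NASH vehicle libraries. Control 3 stood apart on the third component, which held 7.28%. In that library, RNAs of the smooth muscle gene Acta2 reached 138.9 CPM against 1.5 to 2.28 CPM in the other 3 control libraries. Genes detected per library numbered 19359 ± 414 in control, 21627 ± 335 in NASH vehicle and 21137 ± 696 in CDDO-Me (mean ± SD, n = 4 each), and the 10 most abundant genes held 16.0% ± 1.3, 13.4% ± 0.9 and 14.1% ± 1.2 of the reads. Libraries of NASH livers held RNA of more genes at similar depth, and the scaling factors of the trimmed mean of M values (TMM) were 0.78 ± 0.04 in control, 1.20 ± 0.08 in NASH vehicle and 1.08 ± 0.11 in CDDO-Me. Every fold change below is relative to that scaling.

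NASH vehicle livers were first set against control livers, which asks what the disease model changed. RNAs of macrophages, chemokines, collagens and dividing cells rose many-fold, and RNAs of fat synthesis, bile acid synthesis, drug metabolism and the mitochondrial respiratory chain fell. Adgre1, which encodes the macrophage surface protein F4/80, rose from 6.42 ± 1.46 to 66.2 ± 10.7 CPM (mean ± SD, n = 4 each), a log2 fold change of 3.36 ± 0.16 (SE). Col1a1, which encodes a chain of type I collagen, rose from 23.5 ± 12.5 to 443.6 ± 59.6 CPM (log2 fold change 4.23 ± 0.41). Scd1, which encodes the desaturase that makes monounsaturated fatty acids, fell from 11588 ± 2966 to 180.0 ± 96.4 CPM (log2 fold change -6.01 ± 0.43). Of the 16456 genes tested, 4874 were higher and 4945 were lower in NASH vehicle livers by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 3394 and 1273 of them changed at least 2-fold. Camera called 26 of the 34 gene lists tested, and 0 with an estimated correlation.

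Scaling set the balance of these calls. For genes higher, NASH vehicle against control and genes lower, NASH vehicle against control, library totals alone gave 9908 and 1326 (88.2% higher), and the median log2 fold change of all genes moved from -0.01 to 0.62. Limma-trend on log2(TPM + 1) gave 10905 higher and 873 lower (92.6% higher), with a median of 0.51.

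All 19 macrophage markers rose in NASH vehicle livers, with a median log2 fold change of 3.57 (camera adjusted p = 1.3e-31, adjusted p = 0.065 with an estimated correlation). Mpeg1, which encodes a pore-forming protein of macrophages, rose by a log2 fold change of 3.86 ± 0.15, and C1qc, a chain of complement C1q, by 3.22 ± 0.16. Of 18 markers of lipid-associated and monocyte-derived macrophages, 16 rose and 2 did not pass (median 4.38, camera adjusted p = 6.1e-22, adjusted p = 0.065 with an estimated correlation). They included Trem2, a lipid-sensing receptor (0.55 ± 0.24 to 91.1 ± 25.2 CPM), Gpnmb (0.34 ± 0.11 to 678.4 ± 191.2 CPM) and Ms4a7 (log2 fold change 6.44 ± 0.35). Of 20 chemokines and receptors of monocytes and macrophages, 17 rose and 3 did not pass, or 18 and 2 adjusted over the list alone (median 3.55, camera adjusted p = 3.1e-12, adjusted p = 0.065 with an estimated correlation). Among them, Ccl2, the chemokine that draws monocytes out of the blood, rose from 0.28 ± 0.11 to 7.18 ± 1.16 CPM, and its receptor Ccr2 rose from 0.94 ± 0.43 to 21.5 ± 3.5 CPM. Only 40.5% of the Ccl2 reads mapped to a single place, so its level is uncertain.

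Kupffer cells are the resident macrophages of the liver, and their markers moved both ways. Of 14, 5 rose, 5 fell and 4 did not pass, with a median log2 fold change of 0.13 and a mean of -0.01 (camera adjusted p = 0.66). Cd5l rose (28.7 ± 5.4 to 142.2 ± 42.6 CPM), and Cd163, a hemoglobin scavenger receptor, fell (6.32 ± 1.92 to 1.02 ± 0.73 CPM). Clec4f, a receptor found on Kupffer cells, had 45.3 ± 9.0 CPM in control and 45.5 ± 43.4 CPM in NASH vehicle livers (log2 fold change 0.01 ± 0.56, edgeR adjusted p = 0.99). NASH vehicle 1 alone held 110.0 CPM of Clec4f against 16.2 to 30.4 CPM in the other 3, and without it the log2 fold change was -0.91 (Clec4f, NASH vehicle against control, edgeR adjusted p = 0.064; 0.064 to 1 over all alternatives).

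Other leukocyte markers rose as well. The neutrophil list had 6 of 7 genes higher and 1 not passing (median 3.76, camera adjusted p = 0.0031, adjusted p = 0.16 with an estimated correlation), including Csf3r, the receptor of granulocyte colony-stimulating factor (log2 fold change 3.79 ± 0.25), and S100a8 (3.76 ± 0.56). T and NK cell markers had 14 of 16 higher and 2 not passing (median 2.43, camera adjusted p = 0.0027, adjusted p = 0.30 with an estimated correlation). Dendritic cell markers had 12 of 14 higher and 2 not passing (median 3.03, camera adjusted p = 5.2e-08, adjusted p = 0.13 with an estimated correlation), among them H2-Ab1, a chain of an antigen-presenting molecule (3.14 ± 0.23). Of 22 inflammatory cytokine and NF-kB target genes, 20 rose, 1 fell and 1 did not pass (median 2.38, camera adjusted p = 7.5e-13, adjusted p = 0.065 with an estimated correlation). Il1rn, which encodes the interleukin-1 receptor antagonist, rose by 5.07 ± 0.32, and Tnf, the gene of tumor necrosis factor, by 5.17 ± 0.59 from 6 reads in all control libraries together. On the TPM scale the neutrophil and the T and NK cell lists were not called (camera adjusted p = 0.13 and 0.12). Ranges over all alternatives were 5.3e-06 to 0.16 and 7.9e-05 to 0.30. Their low ends are adjusted p of fry, which does not set a list against the other genes as camera does. Of 22 interferon-induced genes, 19 rose and 3 did not pass, or 20 and 2 adjusted over the list alone (median 1.80, camera adjusted p = 1.0e-07, adjusted p = 0.21 with an estimated correlation), and of 14 adhesion molecules of leukocyte entry 9 rose, 1 fell and 4 did not pass (median 2.45, camera adjusted p = 1.6e-06, adjusted p = 0.095 with an estimated correlation). B and plasma cell markers were not called (2 of 10 higher, camera adjusted p = 0.25).

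Genes of scar matrix rose together. Of 35 fibrillar matrix and fibrogenic genes, 30 rose and 5 did not pass, or 31 and 4 adjusted over the list alone (median 2.61, camera adjusted p = 8.3e-17, adjusted p = 0.15 with an estimated correlation). Col5a1 (log2 fold change 2.46 ± 0.16), Sparc (2.53 ± 0.20), Tgfb1, a growth factor that drives collagen synthesis (2.26 ± 0.19), and Timp1, an inhibitor of matrix-degrading enzymes, rose. Timp1 had 10 reads in the control libraries together and 1880 in the NASH vehicle libraries, a ratio of 123.0 in CPM (95% counting interval 66.7 to 257.0), and it overlaps Syn1 on the other strand. Stellate cells are the collagen-making pericytes of the liver, and 12 of their 14 markers rose, 1 fell and 1 did not pass (median 1.44, camera adjusted p = 3.6e-05, adjusted p = 0.13 with an estimated correlation), with Pdgfrb at 2.44 ± 0.21. Acta2, a marker of activated stellate cells that smooth muscle also makes, did not pass (log2 fold change -1.98 ± 1.36, edgeR adjusted p = 0.23). Without control 3 it rose by 2.23 (Acta2, NASH vehicle against control, edgeR adjusted p = 0.028; 0.00014 to 0.99 over all alternatives).

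Of 31 cell cycle genes, 28 rose and 3 did not pass (median 2.51, camera adjusted p = 1.1e-12, adjusted p = 0.13 with an estimated correlation), including Mki67 (0.86 ± 0.39 to 19.9 ± 3.3 CPM) and Ccnb1, the gene of cyclin B1 (0.29 ± 0.12 to 6.64 ± 2.17 CPM). Of 21 acute phase proteins, which the liver secretes in inflammation, 12 rose, 8 fell and 1 did not pass (camera adjusted p = 0.0065, adjusted p = 0.49 with an estimated correlation). Lcn2, which binds bacterial iron carriers, rose from 1.52 ± 0.49 to 323.1 ± 68.4 CPM. The camera call of that list ended without NASH vehicle 1 (adjusted p = 0.096), with limma-voom (0.23) and on the TPM scale (0.31). Of 20 genes of endoplasmic reticulum stress and the integrated stress response, 9 rose, 7 fell and 4 did not pass, or 10, 8 and 2 adjusted over the list alone (camera adjusted p = 0.34), and Fgf21, a liver hormone of energy balance, rose from 0.60 ± 0.38 to 24.5 ± 11.1 CPM. Of 20 liver injury and fetal liver genes, 16 rose and 4 did not pass (median 1.89, camera adjusted p = 9.0e-08, adjusted p = 0.13 with an estimated correlation). Of 15 cholangiocyte and ductular markers, 5 rose and 10 did not pass (camera adjusted p = 0.043, adjusted p = 0.61 with an estimated correlation), and that call ended at 0.052 to 0.076 without control 1, 2 or 4 or NASH vehicle 2 or 4. Control 3 had a mean log2 CPM of 4.28 over these markers, against 0.53 to 1.28 in the other control libraries. Without control 3 the camera adjusted p was 7.6e-07 (7.6e-07 to 0.70 over all alternatives).

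Genes of hepatocyte function fell. Of 20 hepatocyte markers, 18 fell and 2 did not pass (median -1.15, camera adjusted p = 1.0e-07, adjusted p = 0.27 with an estimated correlation), including Arg1, the last enzyme of the urea cycle (log2 fold change -2.27 ± 0.26), and Ttr, a plasma carrier protein (-1.51 ± 0.18). Of 20 genes of fatty acid and triglyceride synthesis, 18 fell, 1 rose and 1 did not pass (median -1.55, camera adjusted p = 4.8e-10, adjusted p = 0.13 with an estimated correlation), and Fasn, the gene of fatty acid synthase, fell by 1.60 ± 0.21 on the log2 scale. Of 24 genes of cholesterol synthesis and uptake, 17 fell and 7 did not pass (median -0.76, camera adjusted p = 1.4e-05, adjusted p = 0.32 with an estimated correlation). Insig1, which holds the sterol sensor in the endoplasmic reticulum, fell by 1.53 ± 0.17. Of 26 nuclear genes of the mitochondrial respiratory chain, 26 fell (median -0.99, camera adjusted p = 7.7e-11, adjusted p = 0.27 with an estimated correlation), with Ndufv2 of complex I at -0.95 ± 0.11. With library totals alone, 23 of these 26 still fell, with a median of -0.37, and on the TPM scale the value of Ndufv2 was -0.15 (Ndufv2, NASH vehicle against control, limma adjusted p = 0.12).

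RNAs of bile acid and drug metabolism fell in the same livers, with medians near that of hepatocyte markers (-1.15). No metabolic list was tested against hepatocyte markers. Whether a list fell beyond hepatocyte RNA as a whole was thus not tested. Of 20 genes of bile acid synthesis and transport, 15 fell, 2 rose and 3 did not pass, or 16, 2 and 2 adjusted over the list alone (median -1.23, camera adjusted p = 1.0e-09, adjusted p = 0.13 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, fell by 3.68 ± 0.19, the transporter gene Slco1a1 fell by 4.53 ± 0.30, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 51.1 ± 15.2 to 17.98 ± 9.68 CPM. The call of Cyp7a1 ended narrowly on the TPM scale (adjusted p = 2.1e-05 to 0.050 over all alternatives). Of 21 drug-metabolizing cytochromes and related genes, 18 fell, 2 rose and 1 did not pass (median -1.15, camera adjusted p = 2.6e-08, adjusted p = 0.13 with an estimated correlation), with Cyp2c29 at -5.09 ± 0.20. Genes of amino acid catabolism (18 of 20 lower, median -1.40, camera adjusted p = 1.0e-07), of choline and methionine metabolism (17 of 22 lower and 2 higher, median -1.08, adjusted p = 1.3e-05) and of periportal hepatocytes (9 of 14 lower and 1 higher, median -1.35, adjusted p = 0.0024) fell too, each at adjusted p of 0.27 to 0.40 with an estimated correlation. The periportal list shares several genes with the amino acid list, Arg1 among them. Sinusoidal endothelial markers had 12 of 16 lower, 1 higher and 3 not passing (median -0.92, camera adjusted p = 0.0015, adjusted p = 0.36 with an estimated correlation), among them Dnase1l3, a nuclease that degrades DNA outside cells (-1.70 ± 0.20). Genes of fatty acid oxidation had 16 of 25 lower, 3 higher and 6 not passing (median -0.56, camera adjusted p = 0.0015, adjusted p = 0.49 with an estimated correlation), and Acsl1, which activates fatty acids, fell by 2.03 ± 0.18. With library totals alone this list had 9 lower and 5 higher, and its median turned to 0.06.

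NRF2 target genes moved both ways in NASH vehicle livers. Of 39, 13 rose, 13 fell and 13 did not pass (median -0.03, mean 0.35, camera direction up, adjusted p = 0.65). Nqo1, a quinone reductase and common readout of NRF2, rose from 5.56 ± 0.66 to 13.4 ± 1.1 CPM, Srxn1, which repairs oxidized peroxiredoxins, by 1.74 ± 0.16, and Hmox1, the gene of heme oxygenase-1, by 3.23 ± 0.18. Me1, which makes NADPH, fell by 2.91 ± 0.17. Gclm, a subunit of the enzyme that starts glutathione synthesis, had a log2 fold change of -0.66 ± 0.11 and Keap1 of -0.38 ± 0.09, but both signs turned on the TPM scale, and that of Keap1 also with library totals alone. Of the reads of Gclm and Keap1, 37.2% and 62.1% mapped to a single place. Nfe2l2 itself rose by 0.69 ± 0.11. Of 15 lipid droplet proteins, 4 rose, 6 fell and 5 did not pass (median -0.14, mean 0.03, camera adjusted p = 0.88). Cidec, which fuses lipid droplets, rose by 2.54 ± 0.31, and Plin2, their coat protein, was at 637 ± 139 CPM in control and 745 ± 125 CPM in NASH vehicle livers (edgeR adjusted p = 0.35). Plin2 was called higher on the TPM scale and with library totals alone (adjusted p = 0.00035 to 0.73 over all alternatives). The medians of the NRF2 and lipid droplet lists turned to 0.60 and 0.48 with library totals alone.

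Among abundant genes with no overlap between the groups, the 8 with the largest fitted rises included Gpnmb, at chromosome 6, 49036546 to 49070929 of GRCm38 (log2 fold change 10.95 ± 0.43), Mmp12, a macrophage elastase (10.29 ± 0.57), and Vsig8. Vsig8 had 4 reads in the control libraries together and 2351 in the NASH vehicle libraries, a ratio of 384.6 in CPM (95% counting interval 150.02 to 1412.8), with 53.3% of its reads in introns. The other 5 had 0 reads in the control libraries, so their rank among the 8 is not known. Against the floor of 3 reads over the group, Sprr1a was at least 138-fold, Clec4e at least 77.9-fold, Slfn4 at least 69.8-fold, Serpinb9b at least 60.9-fold and Trim29 at least 53.7-fold higher in NASH vehicle livers. The largest falls were those of Hsd3b5, a steroid dehydrogenase of male mouse liver (239.5 ± 43.3 to 0.13 ± 0.06 CPM), and of major urinary protein genes, which encode pheromone carriers. Log2 fold changes were -9.31 ± 0.57 for Mup7, -9.33 ± 1.06 for Mup15, -7.53 ± 0.57 for Mup12, -7.25 ± 0.60 for Mup17 and -6.74 ± 0.84 for Mup9. Copies of this family are nearly identical, and 10.3% to 74.6% of their reads mapped to a single place, as did 27.5% of those of Hsd3b5, so the share of each copy is uncertain. Pitx3 had 75.2% of its reads in introns and lies beside Elovl3, and 1264 of the 1343 reads of Shh came from control 3. The call of Shh ended on the TPM scale and with limma-voom (limma adjusted p = 0.094 and 0.080 for Shh, NASH vehicle against control; 0.00098 to 0.094 over its alternatives).

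CDDO-Me livers were then set against NASH vehicle livers, the comparison that the design text names. NRF2 target genes and drug-metabolizing cytochromes rose, RNAs of macrophages, fibrillar matrix and interferon response fell, and sinusoidal endothelial markers rose. Nqo1 rose from 13.4 ± 1.1 to 124.0 ± 20.97 CPM (log2 fold change 3.21 ± 0.13), Adgre1 fell from 66.2 ± 10.7 to 21.4 ± 1.8 CPM (-1.63 ± 0.15) and Col1a1 fell from 443.6 ± 59.6 to 166.9 ± 60.2 CPM (-1.41 ± 0.36). Cyp2a5, a cytochrome that oxidizes coumarin, rose from 247 ± 46 to 7725 ± 1424 CPM (4.97 ± 0.28). Of 16456 genes tested, 1545 were higher and 1191 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 397 and 362 of them changed at least 2-fold. Camera called 19 lists, and with an estimated correlation 2, those of NRF2 targets and of drug-metabolizing cytochromes. The mean log2 CPM of 9 of the 19 called lists had no overlap between the groups. These lists were called on the same libraries, so this is no separate evidence, and 21.6% of all tested genes had none. The groups overlapped for lipid-associated macrophage, T and NK cell, dendritic cell, matrix, stellate cell, adhesion, bile acid, respiratory chain, acute phase and liver injury lists.

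The balance of calls again moved with the scaling. Library totals alone gave 926 higher and 1589 lower (36.8% higher, median of all genes -0.16), and limma-trend on log2(TPM + 1) gave 779 and 2607 (23.01% higher, median -0.16). Leaving out 1 library at a time gave 930 to 1972 higher and 617 to 1498 lower. Counts fell by over 1.5 times without NASH vehicle 2 (767 lower), NASH vehicle 3 (959 higher, 740 lower), NASH vehicle 4 (930 and 639), CDDO-Me 2 (937 and 658) or CDDO-Me 3 (947 and 617), as given for genes higher, CDDO-Me against NASH vehicle and genes lower, CDDO-Me against NASH vehicle. Without control 3 and CDDO-Me 4, libraries chosen after seeing the data, 2211 genes were higher and 2004 lower.

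**Figure D1:**
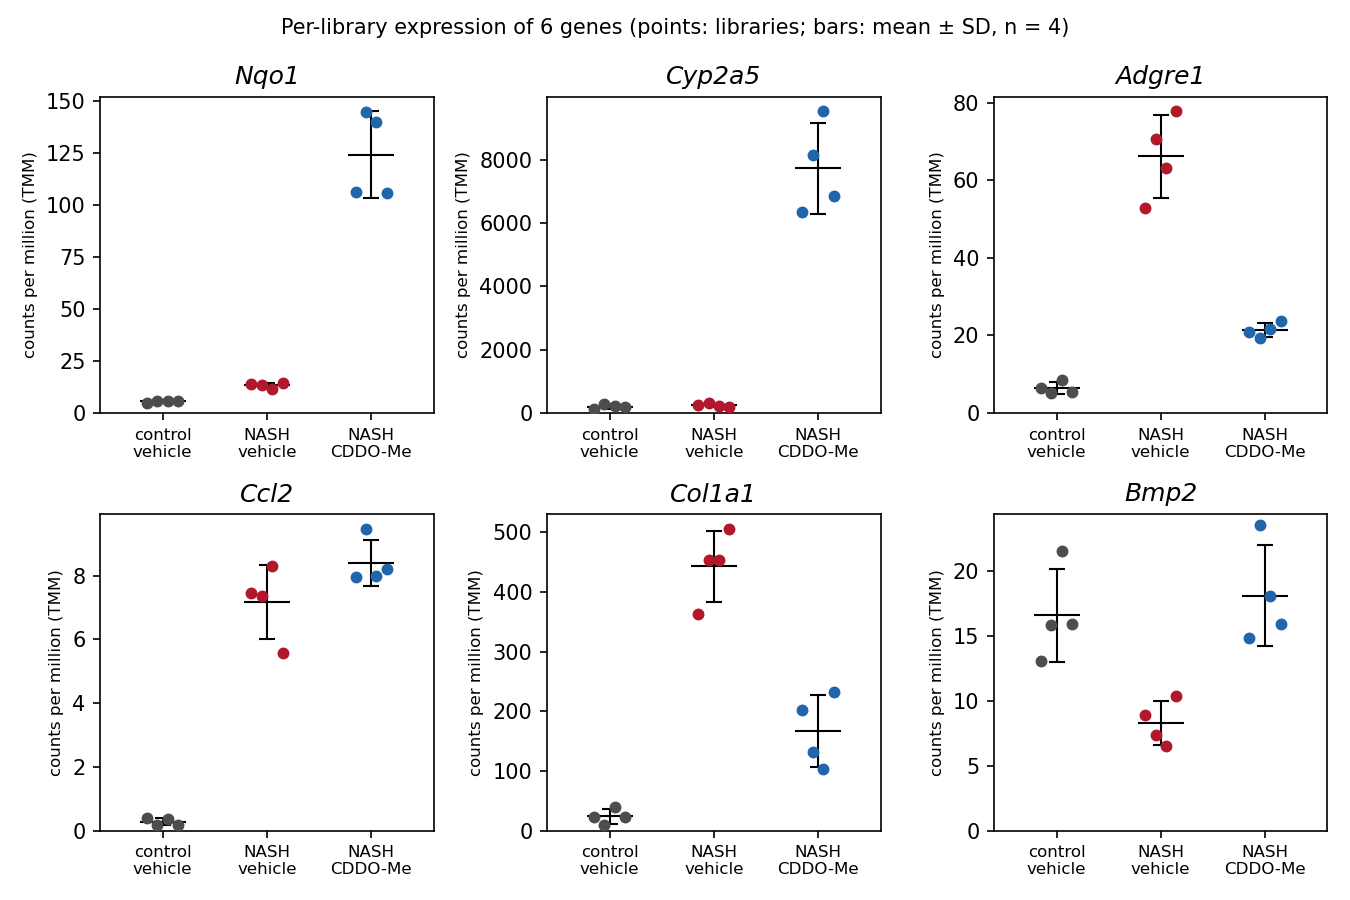
CPM (TMM-scaled counts, vertical axis from 0) of 6 genes in the 12 libraries, grouped as control vehicle, NASH vehicle and NASH CDDO-Me. Points are libraries and bars are mean ± SD (n = 4), and Nqo1 and Cyp2a5 stand far higher in CDDO-Me (124.0 and 7725 CPM), Adgre1 and Col1a1 lie between the other groups, Ccl2 stays near its NASH vehicle level (8.40 against 7.18 CPM) and Bmp2 is close to control (18.1 against 16.6 CPM).

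Of 39 NRF2 target genes, 36 rose, 1 fell and 2 did not pass in CDDO-Me livers (median log2 fold change 1.46, camera adjusted p = 5.5e-100, adjusted p = 0.0051 with an estimated correlation). Cbr1, a carbonyl reductase, rose by 3.22 ± 0.16, Gclm from 176.6 ± 11.6 to 428.6 ± 57.8 CPM, and Abcc4, an efflux pump, from 11.7 ± 1.1 to 308.6 ± 54.0 CPM. Gstm1, a glutathione transferase of a family with near-identical copies, rose by 3.22 ± 0.17. The 1 member that fell was Hmox1 (91.7 ± 18.6 to 47.9 ± 10.7 CPM, log2 fold change -0.94 ± 0.17). Nfe2l2 fell by 0.40 ± 0.11, and Keap1 was at 65.4 ± 2.5 and 77.2 ± 9.6 CPM (edgeR adjusted p = 0.083; 0.014 to 0.94 over all alternatives). Keap1 passed without CDDO-Me 4. The call of Nfe2l2 (edgeR adjusted p = 0.029) ended without NASH vehicle 2 or 3 or without CDDO-Me 1, 2 or 3, at adjusted p of 0.060 to 0.095.

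Of 19 macrophage markers, 14 fell and 5 did not pass, or 15 and 4 adjusted over the list alone (median -1.03, camera adjusted p = 9.8e-18, adjusted p = 0.20 with an estimated correlation). Fcgr1, a high-affinity antibody receptor, fell by 1.82 ± 0.17, C1qc fell by 1.30 ± 0.15 and C1qa fell by 1.22 ± 0.15. Of 18 lipid-associated and monocyte-derived macrophage markers, 7 fell and 11 did not pass, or 9 fell, 1 rose and 8 did not pass adjusted over the list alone (median -0.77, camera adjusted p = 1.8e-05, adjusted p = 0.34 with an estimated correlation). The mean log2 CPM of CDDO-Me 4 over this list (6.17) lay above that of NASH vehicle 1 (5.91). Trem2 fell from 91.1 ± 25.2 to 40.5 ± 11.6 CPM, Ms4a7 fell by 1.90 ± 0.25 and Gpnmb fell by 1.40 ± 0.26. Of 20 monocyte and macrophage chemokines and receptors, 7 fell and 13 did not pass, or 9 and 11 adjusted over the list alone (median -0.88, camera adjusted p = 4.9e-06, adjusted p = 0.20 with an estimated correlation). Ccl3 fell by 2.05 ± 0.43 and Ccl4 fell by 2.29 ± 0.40. Ccl2 was at 7.18 ± 1.16 and 8.40 ± 0.72 CPM (edgeR adjusted p = 0.46), and Ccr2 at 21.5 ± 3.5 and 15.8 ± 7.0 CPM (edgeR adjusted p = 0.35).

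Kupffer cell markers did not move as a group. Of 14, 1 rose (Slc40a1, the iron exporter ferroportin, 109.5 ± 6.0 to 216.8 ± 26.03 CPM), 1 fell (C6, a complement component, 164.1 ± 28.9 to 29.7 ± 13.2 CPM) and 12 did not pass, or 2, 2 and 10 adjusted over the list alone (camera adjusted p = 0.91). C6 is also a member of the male-type liver list described below. Clec4f was at 45.5 ± 43.4 and 63.2 ± 28.5 CPM (edgeR adjusted p = 0.62). Without NASH vehicle 1 it rose by 1.39 on the log2 scale (Clec4f, CDDO-Me against NASH vehicle, edgeR adjusted p = 0.033; 0.033 to 0.86 over all alternatives).

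Inflammatory and interferon genes fell. Of 22 inflammatory cytokine and NF-kB target genes, 11 fell and 11 did not pass (median -0.61, camera adjusted p = 4.9e-06, adjusted p = 0.20 with an estimated correlation). Nfkb1, a subunit of NF-kB, fell by 0.56 ± 0.08 and Il1rn fell by 1.20 ± 0.25. Tnf was at 2.35 ± 0.27 and 1.21 ± 0.37 CPM (edgeR adjusted p = 0.14) and passed with DESeq2, limma-voom, TPM, the 8 libraries of the 2 groups or 10 libraries. Of 22 interferon-induced genes, 16 fell and 6 did not pass, or 18 and 4 adjusted over the list alone (median -0.86, camera adjusted p = 3.3e-12, adjusted p = 0.20 with an estimated correlation), with Oas1a, a sensor of viral RNA, at -1.60 ± 0.20. Of 21 acute phase proteins, 10 fell, 3 rose and 8 did not pass, or 10, 4 and 7 adjusted over the list alone (median -0.42, camera adjusted p = 0.00069, adjusted p = 0.48 with an estimated correlation), among them Steap4 (-1.36 ± 0.17) and Lcn2 (-1.25 ± 0.18).

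Of 35 fibrillar matrix and fibrogenic genes, 19 fell and 16 did not pass, or 25 and 10 adjusted over the list alone (median -0.90, camera adjusted p = 6.7e-13, adjusted p = 0.29 with an estimated correlation). Here too CDDO-Me 4 (mean log2 CPM 5.66) lay above NASH vehicle 1 (5.55), and CDDO-Me 4 also had the highest biliary and smooth muscle RNA of its group. Col14a1 fell by 0.89 ± 0.13 and Col5a1 fell by 0.99 ± 0.15. Tgfb1 fell from 37.0 ± 6.0 to 23.4 ± 6.8 CPM. Timp1 was at 12.5 ± 3.9 and 6.06 ± 2.42 CPM (edgeR adjusted p = 0.078; 0.0081 to 0.22 over all alternatives). Timp1 passed with DESeq2, limma-voom, the TPM scale and the 8 libraries of the 2 groups, and without control 3, NASH vehicle 1 or CDDO-Me 4. Acta2 was at 9.23 ± 0.96 and 15.6 ± 18.1 CPM (edgeR adjusted p = 0.75). It was at 42.4 CPM in CDDO-Me 4, and its log2 fold change turned from 0.76 to -0.46 without CDDO-Me 4 (Acta2, CDDO-Me against NASH vehicle, edgeR adjusted p = 0.86; 0.30 to 0.97 over all alternatives). The call of Col1a1 (edgeR adjusted p = 0.022) ended at 0.051 to 0.074 without NASH vehicle 2, 3 or 4 or CDDO-Me 2 or 3, and that of Tgfb1 (0.023) at 0.058 to 0.075 without NASH vehicle 2, 3 or 4 or CDDO-Me 1, 2 or 3. Of 14 stellate cell markers, 6 fell, 1 rose and 7 did not pass (median -0.42, camera adjusted p = 0.0030, adjusted p = 0.34 with an estimated correlation).

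Sinusoidal endothelial markers moved the other way. Of 16, 11 rose and 5 did not pass, or 12 rose, 1 fell and 3 did not pass adjusted over the list alone (median 0.89, camera adjusted p = 1.4e-08, adjusted p = 0.23 with an estimated correlation). Bmp2, an endothelial signal that sets the iron hormone hepcidin, rose from 8.29 ± 1.71 to 18.1 ± 3.9 CPM, Tek, the receptor of angiopoietins, from 4.71 ± 1.20 to 9.13 ± 1.16 CPM, and Dnase1l3 by 1.12 ± 0.20. Of 14 adhesion molecules of leukocyte entry, 5 fell, 1 rose and 8 did not pass, or 6, 1 and 7 adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.37 with an estimated correlation). The member that rose was Pecam1, which the endothelial list holds too (0.91 ± 0.20). This call ended with library totals alone (camera adjusted p = 0.077; 0.0035 to 0.37 over all alternatives). T and NK cell markers (4 of 16 lower, camera adjusted p = 0.049), dendritic cell markers (2 of 14 lower, 0.018) and liver injury genes (4 of 20 lower, 0.030) were called narrowly, and none of them with an estimated correlation (adjusted p = 0.55, 0.48 and 0.55). The first was lost without any of 9 single libraries (0.058 to 0.16; 0.0086 to 0.55 over all alternatives), the next without CDDO-Me 3 (0.063; 0.0028 to 0.48 over all alternatives) and the last without CDDO-Me 1 (0.074; 0.0078 to 0.55 over all alternatives).

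Of 21 drug-metabolizing cytochromes and related genes, 15 rose and 6 did not pass, or 17 and 4 adjusted over the list alone (median 1.30, camera adjusted p = 2.8e-24, adjusted p = 0.034 with an estimated correlation). Cyp1a2, which metabolizes caffeine, rose from 315 ± 14 to 3173 ± 441 CPM and Cyp1a1 from 0.55 ± 0.07 to 4.32 ± 0.47 CPM. Of 25 genes of fatty acid oxidation, 13 rose and 12 did not pass, or 18 and 7 adjusted over the list alone (median 0.64, camera adjusted p = 6.5e-09, adjusted p = 0.34 with an estimated correlation), including Pex11a of peroxisomes (1.35 ± 0.14) and Vnn1 (1.08 ± 0.16). Of 26 respiratory chain genes, 16 rose and 10 did not pass, or 21 and 5 adjusted over the list alone (median 0.48, camera adjusted p = 1.3e-08, adjusted p = 0.48 with an estimated correlation), with Uqcrfs1 of complex III at 0.72 ± 0.14. Of 14 pericentral hepatocyte genes, 6 rose, 1 fell and 7 did not pass (median 0.37, camera adjusted p = 4.9e-06, adjusted p = 0.20 with an estimated correlation), with Glul, the gene of glutamine synthetase, at 0.77 ± 0.11. The pericentral list shares genes with the drug-metabolizing list, Cyp1a2 among them, so its call is not a separate result.

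Of 20 genes of bile acid synthesis and transport, 6 rose, 1 fell and 13 did not pass (median 0.25, camera adjusted p = 0.0027, adjusted p = 0.48 with an estimated correlation). Akr1d1, a steroid reductase of bile acid synthesis, rose by 1.33 ± 0.13, and the member that fell was Cyp7a1 (17.98 ± 9.68 to 4.67 ± 1.63 CPM). Fatty acid and triglyceride synthesis (2 rose, 3 fell and 15 of 20 did not pass, or 2, 4 and 14 adjusted over the list alone, camera adjusted p = 0.50), cholesterol synthesis (1, 1 and 22 of 24, adjusted p = 0.27) and cell cycle genes (0, 3 and 28 of 31, or 0, 1 and 30 adjusted over the list alone, adjusted p = 0.17) were not called. Cholesterol synthesis passed as lower without CDDO-Me 1 (camera adjusted p = 0.011; 0.011 to 0.89 over all alternatives) and the cell cycle list without CDDO-Me 2 (0.013; 0.013 to 0.83 over all alternatives). Hepatocyte markers were not called either (5 of 20 higher and 1 lower, camera adjusted p = 0.088), but passed without NASH vehicle 1 or CDDO-Me 4 (0.0013 and 0.012). Within fat synthesis, Scd1 fell further, from 180.0 ± 96.4 to 14.04 ± 4.86 CPM, Me1 rose by 0.73 ± 0.16 and Fasn was at 148.2 ± 19.8 and 95.5 ± 31.2 CPM (edgeR adjusted p = 0.052; 0.0075 to 0.15 over all alternatives). Fasn passed in 10 alternatives, among them DESeq2, limma-voom and the TPM scale.

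Among abundant genes with no overlap between the groups, the largest rises were those of Slc22a12, a urate transporter (0.13 ± 0.13 to 97.0 ± 35.6 CPM), Cyp2a4, a steroid hydroxylase (9.67 ± 2.77 to 1401 ± 486 CPM), Tekt5 (0.54 ± 0.19 to 46.5 ± 6.9 CPM), Apela, Gpx2, Cyp2a5, Cyp2b13 and Cbr3. Cyp2a4, at chromosome 7, 26307169 to 26315088, and Cyp2a5, at chromosome 7, 26835305 to 26843548, are near-identical copies, although 90.2% and 91.6% of their reads mapped to a single place. Slc22a12 and Apela rested on 21 and 19 reads in all NASH vehicle libraries together. Slc22a12 overlaps Nrxn2 and Gpx2 overlaps Fntb on the other strand, and 25.5% of Apela and 39.0% of Gpx2 reads mapped to a single place. The largest falls were those of Serpina1e, an alpha-1-antitrypsin copy (278 ± 238 to 6.14 ± 1.70 CPM), Gdf3, Scd1, the fetal RNA H19 (16.4 ± 8.5 to 1.39 ± 0.72 CPM), Raet1d, which shares reads with the overlapping Raet1e, Ntrk2, Fcrls and Scara5. The call of Fcrls ended without CDDO-Me 2 or 3, at edgeR adjusted p of 0.055 and 0.056.

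**Figure D2:**
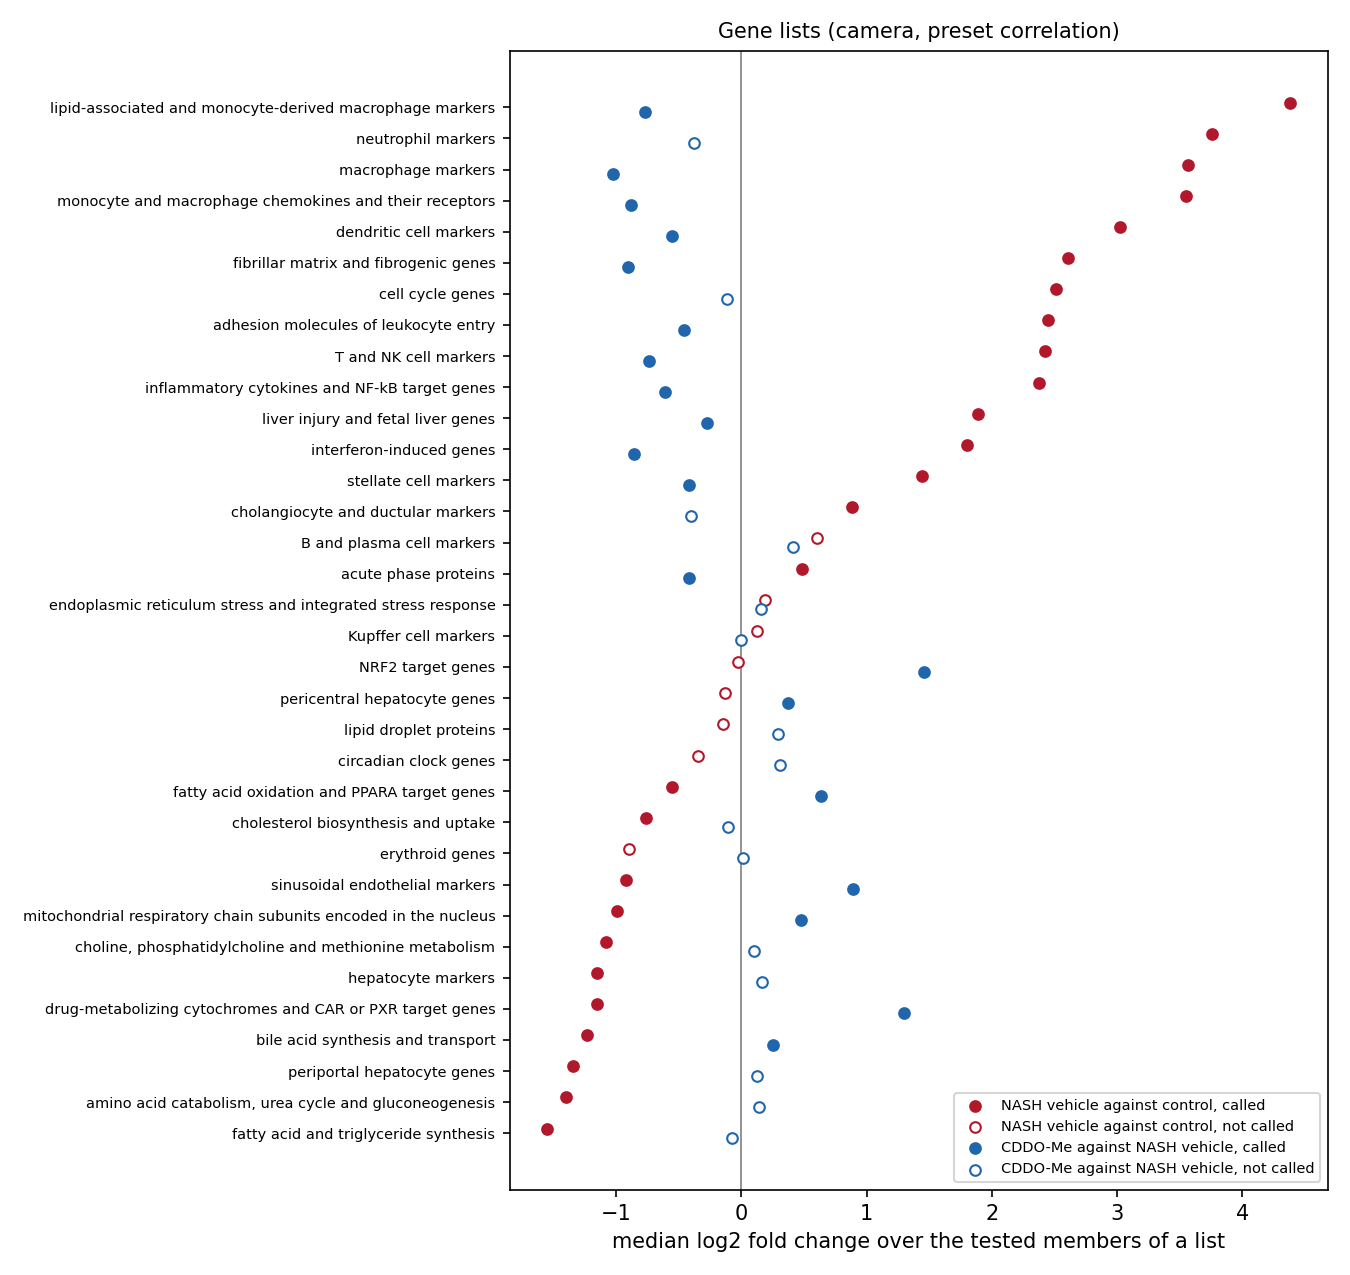
Median log2 fold change over the tested members of each of the 34 gene lists (horizontal axis), with NASH vehicle against control in red and CDDO-Me against NASH vehicle in blue. Filled points were called by camera at adjusted p under 0.05 and open points were not, and the macrophage list lies at 3.57 and -1.03, the NRF2 list at -0.03 and 1.46 and the sinusoidal endothelial list at -0.92 and 0.89, where the first median of the NRF2 list turns sign with library totals alone.

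CDDO-Me livers were last set against control livers, which gives what stayed different under treatment. Macrophage and matrix RNAs were still far above control, NRF2 targets were above control too, and endothelial markers were not called. Adgre1 was at 21.4 ± 1.8 CPM against 6.42 ± 1.46 in control (log2 fold change 1.73 ± 0.15), Col1a1 at 166.9 ± 60.2 against 23.5 ± 12.5 CPM (2.82 ± 0.39) and Nqo1 at 124.0 ± 20.97 against 5.56 ± 0.66 CPM (4.48 ± 0.14). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 4317 genes were higher and 3881 lower, 2851 and 840 of them at least 2-fold. Camera called 23 lists, and 0 with an estimated correlation. For genes higher, CDDO-Me against control and genes lower, CDDO-Me against control, library totals alone gave 8678 and 1125 (88.5% higher, median 0.51) and limma-trend on log2(TPM + 1) 8845 and 812 (91.6% higher, median 0.37).

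Of the macrophage markers, 19 of 19 were higher than in control livers (median 2.64, camera adjusted p = 7.2e-23, adjusted p = 0.076 with an estimated correlation), and of the lipid-associated and monocyte-derived markers 16 of 18 were higher, 1 lower and 1 not passing (median 4.02, camera adjusted p = 5.4e-22, adjusted p = 0.076 with an estimated correlation), with Trem2 at 6.18 ± 0.36, Ccr2 at 4.03 ± 0.37 and Ccl2 at 4.86 ± 0.25. Matrix genes had 28 of 35 higher, 1 lower and 6 not passing, or 29, 1 and 5 adjusted over the list alone (median 1.66, camera adjusted p = 6.9e-10, adjusted p = 0.29 with an estimated correlation), with Timp1 at 5.84 ± 0.58 and Tgfb1 at 1.59 ± 0.19. Tnf was higher by 4.21 ± 0.60. NRF2 targets had 37 of 39 higher and 2 lower (median 1.60, camera adjusted p = 9.5e-32, adjusted p = 0.076 with an estimated correlation), with Hmox1 at 2.29 ± 0.18 and Gclm at 0.62 ± 0.11. Endothelial markers had 2 higher, 3 lower and 11 of 16 not passing, or 2, 2 and 12 adjusted over the list alone (median -0.08, camera adjusted p = 0.61), and with library totals alone 7 higher and 0 lower. Cyp7a1 (-3.45 ± 0.39) and Fasn (-2.23 ± 0.21) were lower, and all 26 respiratory chain genes were lower (median -0.52, camera adjusted p = 9.6e-06, adjusted p = 0.47 with an estimated correlation), of which 3 were lower with library totals alone. Keap1 (log2 fold change -0.15 ± 0.09), Clec4f (0.48 ± 0.56) and Acta2 (-1.22 ± 1.32) did not pass. Acta2 was called higher without control 3 (2.99, edgeR adjusted p = 0.0087; 0.0018 to 0.77 over all alternatives for Acta2, CDDO-Me against control). Keap1 was called higher on the TPM scale (0.43) and with library totals alone (0.31), at 0.0011 to 0.59 over all alternatives for Keap1, CDDO-Me against control. Nfe2l2 (0.29 ± 0.11, edgeR adjusted p = 0.045) and Plin2 (0.52 ± 0.20, 0.045) passed narrowly and were lost without 8 and 7 single libraries, at adjusted p of 0.051 to 0.14 and 0.056 to 0.16.

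Directions of change were compared between the 2 NASH comparisons. Of the 9819 genes called between NASH vehicle and control, 7899 (80.4%) had a fold change of the opposite sign between CDDO-Me and NASH vehicle. Of 2218 genes called in both, 1971 had opposite signs and 247 the same sign. Of the opposite ones, 908 had risen in NASH and fell with CDDO-Me, against 353 for independent lists, and 1063 had fallen and rose, against 464. Both comparisons use the NASH vehicle libraries, and 20 simulations with CDDO-Me unchanged from NASH vehicle gave 55.1% (54.2% to 56.2%) opposite signs and 0 to 1 genes called in both. All simulations here drew each gene independently. They leave out shifts shared by many genes of 1 animal, so real unchanged groups could vary more widely. With the NASH vehicle libraries split into separate pairs, 74.8% to 82.8% had opposite signs over 6 splits, with 532 to 1362 opposite and 106 to 153 same calls. Leaving out 1 library at a time gave 1055 to 2663 opposite calls, and the count fell by over 1.5 times without NASH vehicle 2, 3 or 4 or CDDO-Me 2 or 3. Across genes, which are not independent replicates, the fold changes had a covariance of -0.41, against simulated values of -0.055 with CDDO-Me unchanged and -0.053 with all 3 groups alike. Pearson r was -0.45 and Spearman rho -0.56. Simulations gave -0.11 for both with CDDO-Me unchanged, and -0.49 and -0.45 with all 3 groups alike (-0.51 to -0.45 and -0.46 to -0.43), where noise of the shared libraries is all there is. The observed r lies within the range for groups alike and rho lies beyond it. Of the 1971, 262 that had risen and 566 that had fallen were no longer called against control, and 1143 still were.

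**Figure D3:**
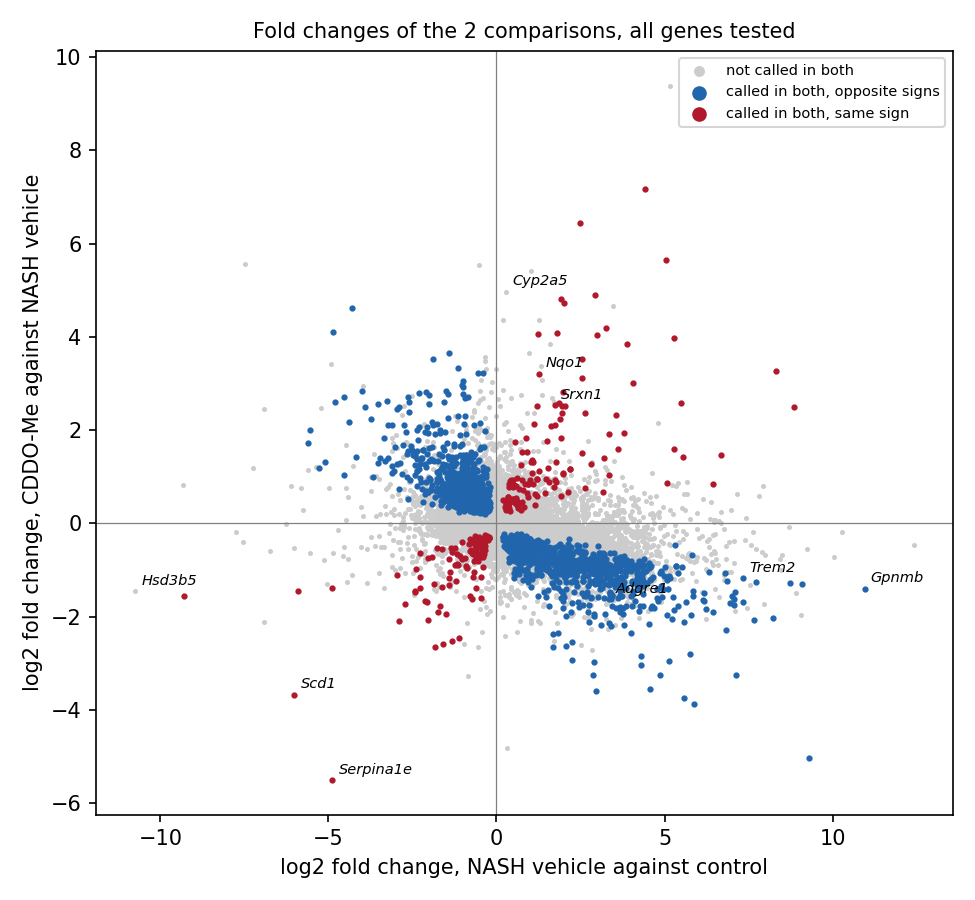
Log2 fold change of each of the 16456 genes tested in NASH vehicle against control (horizontal axis) and in CDDO-Me against NASH vehicle (vertical axis). Blue points are the 1971 genes called in both comparisons with opposite signs, red points the 247 called in both with the same sign and grey points the rest, and the blue points lie at the upper left and lower right.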

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

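The tests of biliary tissue, of smooth muscle and of a wrong label in control 3, of scaling, of cell share and of Kupffer cell genes, and of the exchange of NASH vehicle 1 and CDDO-Me 4 were chosen after the result was seen.

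A library far from the other 3 of its group was found in 30 of 438 groups tested, where chance gives 21.9 (about 1 in 20). NASH vehicle 1 accounts for 9 of them and control 3 for 7. The value given for each is the gap to the nearest library divided by the range of the group.

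Control 3 was far above the other control libraries for Acta2 (138.9 against at most 2.28 CPM, 0.994), Shh (46.8 against at most 1.54 CPM, 0.977), Cbr3 (9.51 against at most 2.08 CPM, 0.980), Gpx2 (3.59 against at most 0.179 CPM, 0.950), Fcrls (0.444 against 0 CPM, 1), Tekt5 (0.296 against at most 0.0447 CPM, 0.849) and adhesion molecules (mean log2 CPM 3.00 against at most 2.48, 0.893). Among the other control libraries, control 2 was highest for Mup9 (1277 against at most 241.2 CPM, 0.978), Oas1a (3.14 against at most 2.15 CPM, 0.843) and Ccl4 (0.0461 against 0 CPM, 1). Ccl4 had 1 read in all control libraries together, so its flag rests on that read alone. Control 1 was highest for stellate cell markers (mean log2 CPM 4.32 against at most 4.22, 0.852) and lowest for Nqo1 (4.57 against at least 5.81 CPM, 0.872).

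NASH vehicle 1 was highest in its group for Clec4f (110.0 against at most 30.4 CPM, 0.849), Cd163 (2.12 against at most 0.742 CPM, 0.900), Mup15 (10.5 against at most 1.80 CPM, 0.830), Mup7 (58.9 against at most 21.1 CPM, 0.842) and Mup9 (9.78 against at most 3.31 CPM, 0.859). It was also highest in mean log2 CPM for bile acid genes (6.72 against at most 6.34, 0.833), drug-metabolizing cytochromes (6.14 against at most 5.65, 0.865) and choline metabolism (7.64 against at most 7.29, 0.957), and lowest for Nfkb1 (53.3 against at least 61.8 CPM, 0.896). NASH vehicle 4 was highest for Lcn2 (424.5 against at most 300.0 CPM, 0.838) and NASH vehicle 2 for Tekt5 (0.824 against at most 0.477 CPM, 0.853).

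Among CDDO-Me libraries, CDDO-Me 1 was highest for Fcgr1 (7.08 against at most 5.29 CPM, 0.833) and cholesterol synthesis (mean log2 CPM 6.54 against at most 6.06, 0.854) and lowest for Abcc4 (228.5 against at least 328.6 CPM, 0.852). CDDO-Me 2 was highest for Ccl2 (9.48 against at most 8.20 CPM, 0.837) and sinusoidal endothelial markers (mean log2 CPM 4.91 against at most 4.48, 0.832). CDDO-Me 3 was highest for Pitx3 (6.79 against at most 1.44 CPM, 0.873) and Slco1a1 (20.6 against at most 14.4 CPM, 0.868).

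Intron reads, which no comparison of the report uses by themselves, made up 1.72 percentage points more of the gene reads in NASH vehicle than in control livers (5.39% ± 0.92 against 3.67% ± 0.55, n = 4 each, exact permutation p = 0.0286, the smallest 4 against 4 libraries can give, adjusted p = 0.075 over 21 tests).

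Over 15 cholangiocyte and ductular markers, the median log2 CPM of control 3 was 3.49 above the mean of the other control libraries, 14 of the 15 were highest there, and the highest value of another control library was -0.58. Over 12 smooth muscle genes it was 3.01 above (11 of 12 highest). Over the 8 whose levels in control 3 had not been seen when the list was written it was 2.64 above (7 of 8 highest, highest other -0.136). Other values of Tagln, 1 of these 8, had been seen by then. CDDO-Me 4 stood above the other CDDO-Me libraries on the same lists, by 0.76 (12 of 15 highest) and 1.43 (11 of 12 highest). A NASH liver with a wrong label is argued against by its macrophage list, which lay 2.81 below the lowest NASH vehicle library (value -2.81). Biliary or gallbladder tissue with smooth muscle in control 3 may be the source, and no biological explanation was tested.

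Macrophage RNAs were lower with CDDO-Me (median -1.03). The scaling between libraries is argued against, since the median closest to 0 over 3 scalings was -1.03 and the lowest was -1.18. RNAs of cell types other than hepatocytes did not all fall, since sinusoidal endothelial markers rose by a median of 0.888. The endothelial minus macrophage mean did not overlap between the groups (gap 0.603). This argues against a lower share of every such cell type only if RNA per cell stayed the same. Bulk RNA cannot show that. The 95% interval of 3 of 14 Kupffer cell genes included the macrophage median, which was taken without its error. The same count was not made for the macrophage markers, so this one has no reference. The interval of C6 (-3.21 to -1.71) lay below that median and that of Slc40a1 (0.75 to 1.22) above it. RNAs of the Kupffer cell list thus did not move alike. Bulk RNA does not assign them to cells, so it cannot decide whether every kind of macrophage was lost equally. Fewer recruited macrophages, or less RNA of these genes per cell, could each give the pattern, and bulk RNA leaves both open.

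Exchanging NASH vehicle 1 and CDDO-Me 4 gave 1464 calls, the highest of the other splits, and points to a structure of the samples. Exchanged labels are argued against, since the mean log2 CPM of the NRF2 list in CDDO-Me 4 was 1.76 above the highest NASH vehicle library. On a scale from the control mean at 0 to the NASH vehicle mean at 1, CDDO-Me 4 lay at 0.934 and NASH vehicle 1 at 0.873, a difference of 0.0602, while the CDDO-Me mean was 0.793 ± 0.112 (SD, n = 4). The scale rests on genes called between these same NASH vehicle and control libraries, which favours values under 1 for CDDO-Me. The CDDO-Me mean is therefore no measure of a return to control. A difference between animals in the extent of the diet response may explain the 1464 calls, and remains a hypothesis.

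Of the 35 splits of each set of 8 libraries, only the labelled 1 gave as many called genes as the labels in each comparison. That is the smallest share 35 splits can give, so chance is unlikely but not excluded. The labels gave 9819, 2736 and 8198 genes, and the highest other split 1, 1464 and 0. For gene lists, 4 of 35 splits gave as many calls as the labels for NASH vehicle against control. It was 16 of 35 for CDDO-Me against NASH vehicle and 12 of 35 for CDDO-Me against control. The labels gave 26, 19 and 23 lists, and the highest other split gave 26 in each. Splits that exchange 1 library keep much of the difference between the groups, so these shares neither exclude chance nor measure it. Splits with as many libraries of both groups on each side gave at most 17, 25 and 16 lists.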

How the results depend on the processing

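Library totals only, total exon reads and the 10 libraries without control 3 and CDDO-Me 4 were tests chosen after the result was seen.

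Of 150 named gene results, 33 kept direction, call and compared size, 82 moved in size only and 35 changed call or direction in at least 1 alternative. Size was compared only with the changed prior count and with mean TPM. In the other alternatives only direction and call were compared. The fold minimum ends the call of every result smaller than it by construction, and such ended calls count among the 35. Of 68 list results, 48 kept their call and 20 did not, with the estimated correlation set aside. In CDDO-Me against NASH vehicle, 2675 of 2736 calls kept call and direction with DESeq2, 2052 with library totals and 1904 on the TPM scale. In NASH vehicle against control, 9481, 6200 and 5541 of 9819 calls did so, in the same order. Of these 9819 calls, 2327 had the opposite sign with library totals, 3142 on the TPM scale and 0 with DESeq2. Of the 2736 calls, 23 had the opposite sign on the TPM scale, 0 with library totals and 0 with DESeq2.

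For genes higher, NASH vehicle against control, limma-trend on TPM gave 10905 and library totals 9908. For genes lower, NASH vehicle against control, they gave 873 and 1326, and the 2-fold minimum 1273. For genes higher, CDDO-Me against NASH vehicle, they gave 779, 926 and 397, and leaving out 1 library 930 to 1972. For genes lower, CDDO-Me against NASH vehicle, TPM gave 2607, the 2-fold minimum 362, DESeq2 1823, the 10 libraries 2004 and leaving out 1 library 617 to 1498. For genes higher, CDDO-Me against control, TPM gave 8845, library totals 8678 and the 2-fold minimum 2851, and for genes lower, CDDO-Me against control, 812, 1125 and 840. The 2-fold minimum lowers counts by construction, library totals moved the median of all genes from -0.01, -0.01 and 0.03 to 0.62, -0.16 and 0.51, and the cause of the other changes was not tested.

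Genes called in both comparisons with opposite signs (opposite_called) numbered 436 with the 2-fold minimum, 3295 with 10 libraries and 1055 to 2663 when 1 library was left out (1274, 1155 and 1055 without NASH vehicle 2, 3 and 4, 1113 and 1081 without CDDO-Me 2 and 3), and those with the same sign (same_called) 84 with the 2-fold minimum. With an estimated correlation, camera called 0, 2 and 0 lists.

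Among the named genes, reversed signs were seen for 4, and where no library is named the cause was not tested. Keap1, NASH vehicle against control was 0.42 on the TPM scale, 0.24 with library totals and 0.41 with mean TPM, and Keap1, CDDO-Me against control 0.43 and 0.31 with the first 2. Gclm, NASH vehicle against control was 0.16 on both TPM scales. Clec4f, NASH vehicle against control was -0.19 with a replicate block, -0.38 with limma-voom and -0.91 to 0.29 when 1 library was left out. Acta2, NASH vehicle against control was 0.039 with the block, 1.16 on the TPM scale, 0.57 with limma-voom, 2.23 with the 10 libraries and -2.38 to 2.23 when 1 library was left out. Acta2, CDDO-Me against NASH vehicle was -0.096 on the TPM scale, -0.46 with the 10 libraries and -0.46 to 1.10 when 1 library was left out. Acta2, CDDO-Me against control was 0.73 with the block, 1.07 on the TPM scale, 0.75 with limma-voom, 1.77 with the 10 libraries and -2.44 to 2.99 when 1 library was left out, and control 3 and CDDO-Me 4 hold most Acta2 reads.

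Depth limits genes such as Slc22a12 and Apela, with 21 and 19 reads in all NASH vehicle libraries together. Simulated data with the depth and spread of these groups recovered 31.3% of 1.5-fold changes, and depth was not varied by itself.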

Other observations

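The tests of the smooth muscle, female-type, male-type and aryl hydrocarbon receptor lists were all chosen after the result was seen.

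Each library held 1537 to 1935 reads of the Y-linked gene Ddx3y and 0 to 6 of Xist, as male animals do, and male-type liver genes fell in NASH livers. Of 24 such genes, 23 were lower and 1 did not pass in NASH vehicle against control (median log2 fold change -3.47, camera adjusted p = 3.8e-23, adjusted p = 0.020 with an estimated correlation), and 23 were lower in CDDO-Me against control (median -3.73). Values of 14 of the 24, among them Hsd3b5, Mup7, Cyp7b1 and Slco1a1, had been seen when the list was written, so this p is not independent evidence. The other 10 were all lower in NASH vehicle against control (median -2.84, camera adjusted p = 1.5e-08, adjusted p = 0.035 with an estimated correlation). Mup3, Mup21 and Cyp4a12b among them belong to families of which other members had been seen. The 10 are therefore not fully independent evidence. Of all 24, 6 rose, 8 fell and 10 did not pass between CDDO-Me and NASH vehicle (camera adjusted p = 0.545). Female-type genes moved both ways in NASH vehicle livers (9 of 19 higher, 7 lower, adjusted p = 0.770), and with CDDO-Me 6 rose, 1 fell and 12 did not pass (adjusted p = 0.00136, adjusted p = 0.058 with an estimated correlation). Among those that rose were Cyp2b9, Cyp2b13, Cyp2a4, Acot3 and Prlr, with log2 fold changes of 3.83, 4.89, 7.19, 2.67 and 1.08 from unique reads alone. Values of 10 of the 19, among them Cyp2a4, Cyp2b13, Cyp2b9 and Ntrk2, had been seen when the list was written. Of the other 9, 1 rose and 8 did not pass (adjusted p = 0.48), so the rise of the list rests on genes seen first. Whether it is part of a general shift from male-type to female-type expression stays open. The male-type genes went both ways with CDDO-Me (median -0.45, adjusted p = 0.545), and some, such as Hsd3b5 at 0.13 CPM in NASH vehicle livers, had little room to fall.

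Of 8 aryl hydrocarbon receptor targets, 4 rose, 1 fell and 3 did not pass with CDDO-Me (camera adjusted p = 1.2e-15, adjusted p = 5.6e-05 with an estimated correlation). The list was written after Cyp1a1, Cyp1a2, Nqo1 and Nfe2l2 were seen, and Nqo1 and Nfe2l2 respond to NRF2 too, so it is not independent evidence. Of the 4 members not seen before, 1 rose and 3 did not pass (adjusted p = 0.48). In NASH vehicle against control, 4 rose, 3 fell and 1 did not pass (adjusted p = 0.770). Of 12 smooth muscle genes, 0 passed in NASH vehicle against control (adjusted p = 0.770) and 0 in CDDO-Me against NASH vehicle (adjusted p = 0.545).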
